A study of Mus musculus with 6 samples.

How the data were processed

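The series holds 1 RNA-seq library from each of 6 CD1 mouse embryos, 3 injected with FGF2 (numbered 6, 7 and 8 in the labels) and 3 injected with vehicle (7, 8 and 9). Per the labels' protocols, RNA was extracted from fixed cryosections on slides, treated with DNase, made into indexed paired-end libraries and sequenced on an Illumina HiSeq 2000. The labels give E13.5 as the age and do not state the time between injection and collection. Per the submitters' processing notes, CASAVA 1.8, TopHat2 2.0.9, Bowtie2 2.1.0.0 and bedtools 2.12.0 were used with the genome build NCBIM37 (mm9), with no role given for each tool. Whether strand was used in counting is not given in the sources used here.

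The deposited count files hold, for 37991 Ensembl genes, whole numbers of alignments that overlap the span from the gene's start to its end, in the column layout of bedtools coverage. Introns are therefore included, reads in overlapping genes count for each of them, and in 5 of the libraries more genes had 2 reads than 1, as separate counting of mates would give. Such counts cannot tell a gene from an antisense or nested neighbour, and 334 of the 799 called genes overlap another span. In vehicle 9 every count is even. The deposited RPKM files give RPKM, reads scaled for gene model length and read number, for each symbol, per the authors' file naming, and the values fit an exonic gene model, but the tool that made them is not given in the sources used here. RPKM values were joined to 34290 genes by a symbol that occurs once. The reference annotation at hand is of another genome build and was not used for coordinates, which are 1-based and as the files give them.

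The counts were tested as deposited with edgeR 4.0.16 in R 4.3.3 (filterByExpr with the group, TMM scaling, glmQLFit with robust estimation, glmQLFTest) over all 6 libraries with no covariate, and p-values were adjusted by the Benjamini-Hochberg method over the 21983 genes kept. CPM values are scaled by the TMM library sizes, log2 fold changes are FGF2 over vehicle with their standard errors, and SDs are over 3 embryos. For genes with at most 3 reads in a group, ratios were computed from summed reads, with a 95% exact binomial interval, or against a floor of 3 reads over the group. These cover at most counting error, since reads without molecular identifiers are not independent molecules. They are too narrow where mates or doubled alignments count as separate reads. A permutation of 3 against 3 embryos cannot give a two-sided p below 0.1, so p-values rest on the model fitted across genes.

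Before the data were examined, 31 gene lists were fixed, of which 30 were tested with camera on voom-transformed counts (limma 3.58.1, preset correlation of 0.01), with an estimated correlation and with fry beside it, adjusted over the lists. The lists cover FGF feedback genes, FGF ligands and receptors, radial glia, outer radial glia, intermediate progenitors, cortical projection neurons, Cajal-Retzius cells, ventral telencephalon, hem and midline, choroid plexus, rostral and caudal patterning, Notch, Wnt targets, DNA replication, mitosis, G1 regulators, extracellular matrix, glia, p53 targets, stress genes, meninges, endothelium, microglia, red blood cells, skin and muscle, diencephalon and midbrain, histones, ribosomal proteins and mitochondrial genes. The last list, of sex-linked markers, is given as reads per embryo. The rule for named genes, also fixed then, takes in each direction the 12 largest changes among called genes with a mean CPM of at least 1 and no overlap between the groups, the 4 members of each list with the smallest p, and a fixed set that holds Fgf2, its receptors and markers of cortical cells. Genes without a gene name are counted and not named. Lhx8 has a second identifier at the same locus with the same values, and is described once. Both identifiers are included in the counts of tested, called and named genes.

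For the count of called genes, 19 alternatives were planned and 3 added after seeing the data. The planned ones were RLE size factors, library totals alone, no low-count filter, a minimum of 1 CPM in 3 libraries, leaving out each embryo in turn, the embryo number as a block, an offset for gene length, removal of mitochondrial, haemoglobin, ribosomal RNA and the 10 most abundant genes, voom with sample quality weights, embryo sex as a covariate, limma on log2(RPKM + 1) and log2(RPKM + 0.1) of genes with an RPKM of at least 1 in 3 libraries, log2(RPKM + 1) without that filter, and DESeq2 1.42.0. The added ones halved the counts of vehicle 9, kept only genes overlapping no other span, and left out genes of the X and Y chromosomes. The scripts were tested on simulated counts with the means and library sizes of these libraries and the dispersion trend across genes. The changed genes were drawn from those with a mean of at least 1 CPM. In that simulation of the FGF2 comparison over 21861 genes, 76 of 100 genes changed 2-fold and 100 of 100 genes changed 4-fold were recovered, with 5 false calls among 181. Spread particular to a gene and outlying libraries were not simulated, so these rates may be better than those in the real data.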

Results

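RNA was measured in the dorsal telencephalon, the part of the embryonic forebrain that forms the neocortex and hippocampus, of CD1 mouse embryos at E13.5. Into the brain ventricles, 3 embryos had received 100 ng of FGF2, a growth factor that acts through FGF receptors, and 3 had received the vehicle, PBS with 0.1% BSA. The RNA came from fixed frozen coronal sections of regions in front of the hippocampus. Total counts over all genes were 81532334, 69853873 and 64631136 for FGF2 embryos 6, 7 and 8, and 61489462, 68101511 and 64225328 for vehicle embryos 7, 8 and 9. Every non-zero count of vehicle 9 was even, against 51% to 51.9% of the non-zero counts in each other library, and its total with the counts halved was 32112664. Y-linked marker genes had 10475 to 16232 reads in the 3 FGF2 embryos and in vehicle 7. Vehicle 8 and vehicle 9 had 22 such reads each, with 58349 and 57904 reads of Xist, the X-inactivation transcript of females.

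The comparison asks which genes differ in expression after FGF2 injection, in a study of cortical folding induced by FGF2. In the FGF2 embryos, 14 of 18 measured genes of the ventral telencephalon, 7 of 10 of the choroid plexus and 8 of 14 of the cortical hem and dorsal midline rose, and 5 of 14 of intermediate progenitors fell. These 4 lists were called with camera's preset correlation and not with an estimated one (adjusted p = 0.196 to 0.222). Of 21983 genes tested with edgeR's quasi-likelihood test, 590 rose and 209 fell past an adjusted p of 0.05. The excess of rises depended on FGF2 8 and on the weighting of libraries. Without FGF2 8 the counts were 964 higher and 979 lower, and with voom and sample quality weights 1273 and 986. With DESeq2 65.8% of the called genes were higher, and in the other alternatives tried 70.5% to 84.5%. Differences of more than 4-fold were seen in 235 of the genes that rose and in 1 of those that fell. The FGF2 and vehicle embryos did not overlap in 6204 of the genes tested (28.2%, where chance gives 10%), among them all 799 called genes, which a small p all but requires. An unadjusted p under 0.05 was found for 4242 genes.

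Among called genes with a mean of at least 1 CPM, a count scaled to the size of its library, the largest rises included that of Gsx1, a patterning gene of the ventral telencephalon on chromosome 5 (148000272 to 148002523, NCBIM37). Gsx1 had 541 reads in the FGF2 embryos and 0 in the vehicle embryos, which makes it at least 157-fold higher against a floor of 3 reads over the group. Shh, a secreted signal of the ventral midline on chromosome 5 (28783355 to 28793641), had 545 against 2 reads, a ratio of 237 with a 95% counting interval of 65.4 to 1960. Pitx1, a gene of pituitary and oral tissue on chromosome 13 (55926415 to 55937553), had 550 against 2 reads, a ratio of 239 (66 to 1980). Both vehicle counts of Shh lay in vehicle 9, where every count is even, so they are not 2 separate reads and its interval is too narrow. The 2 vehicle reads of Pitx1 both lay in vehicle 8 and may be mates of 1 pair, so its interval may be too narrow as well. Onecut3 rose by 6.62 and Ccno, a gene needed to form multiciliated cells, by 6.60 on the log2 scale. Gbx2, a gene of the developing thalamus, rose and stood at 12.1 ± 10.04 CPM (SD, n = 3) against 0.0810 ± 0.0910. Of these genes, the calls of Pitx1 and Gbx2 were lost when some single embryos were left out. Pitx1 reached an adjusted p of up to 0.154 (lost without FGF2 7, FGF2 8 or any 1 vehicle embryo) and Gbx2 of up to 0.103 (lost without FGF2 6, FGF2 8 or any 1 vehicle embryo).

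The largest falls were smaller. Cdon, a co-receptor for Shh on chromosome 9 (35228713 to 35315236), fell by 1.33 ± 0.09 (SE) on the log2 scale, from 569 ± 15.5 to 226 ± 19.7 CPM (SD, edgeR adjusted p = 0.00128). Rlbp1, a retinoid-binding protein, fell by 1.49, Gna14, a G protein subunit, by 1.85, and Slc16a14, a transporter of the monocarboxylate family, by 1.47. Tnn, Actn3, Dct, Tacr3, Pamr1 and Aldoc also fell, by 1.85, 1.62, 1.31, 1.25, 1.21 and 1.21, and each of these 6 lost its call when at least 3 of the 6 embryos were left out singly, at an adjusted p of up to 0.115, 0.113, 0.0722, 0.146, 0.19 and 0.0832. U1 and 5S_rRNA fell too, but the listed copies lie at 35282470 to 35282631 and 35311173 to 35311280 of chromosome 9, inside Cdon, so their reads cannot be told from those of Cdon.

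Genes of the ventral telencephalon and its interneurons, which are normally patterned ventral to the cortex, were higher in the FGF2 embryos. Isl1, a marker of striatal and ventral neurons on chromosome 13 (117088489 to 117099896), rose by 6.34 ± 0.18 (SE, edgeR adjusted p = 1.53e-05), from 0.402 ± 0.0809 to 32.8 ± 3.36 CPM (SD, n = 3). Nkx2-1, which specifies the medial ganglionic eminence, rose by 4.89 to 48.7 ± 19.2 CPM, and Lhx8, which acts with it, was at 12.8 ± 4.13 against 0.0212 ± 0.0367 CPM. Ebf1, a gene of differentiating striatal neurons, rose by 1.67. Of 18 measured members 14 rose, 0 fell and 4 did not pass (17 rose adjusted over the list alone), with a median log2 fold change of 2.82. The list was higher with camera (adjusted p = 7.57e-21, and adjusted p = 0.196 with an estimated correlation). Gad2 and Slc32a1, which make and load the transmitter GABA and were chosen after their values were seen, were among the members that rose, at 87.7 ± 20.4 against 9.61 ± 4.64 CPM and at 21.3 ± 4.5 against 3.2 ± 1.58 CPM.

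Most measured genes of the choroid plexus, the secretory epithelium of the ventricles, rose, from vehicle means of at most 1.445 CPM. Ttr, the transthyretin carrier that this epithelium secretes, rose and stood at 192 ± 176 CPM (SD) against 0.287 ± 0.181, with single FGF2 embryos at 59, 126 and 392 CPM. Clic6 rose by 6.25, Otx2 by 5.36, Htr2c by 7.03 and Sostdc1 to 9.14 ± 4.66 from 0.949 ± 0.349 CPM. Of 10 measured members 7 rose, 1 fell (Aqp1, a water channel, by 1.14) and 2 did not pass, with the same counts adjusted over the list alone and a median of 5.74. The list was higher with camera (adjusted p = 2.09e-05, and adjusted p = 0.196 with an estimated correlation). Without vehicle 7 the calls of Ttr (adjusted p = 0.0627) and Htr2c (0.0509) were lost, and without vehicle 8 that of Sostdc1 (0.064).

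The cortical hem and dorsal midline, a signalling centre at the medial edge of the cortex, had rising members too. Rspo2 and Rspo3, secreted enhancers of Wnt signalling, rose by 4.81 and 2.49, and Wnt8b, a Wnt ligand of the hem, by 5.18. Lmx1a, a transcription factor of the hem and roof plate, rose from 0.697 ± 0.223 to 5.41 ± 1.1 CPM (SD, n = 3), and Wnt5a rose by 1.21. Of 14 measured members 8 rose, 0 fell and 6 did not pass (9 rose adjusted over the list alone), with a median of 1.09. The list was higher with camera (adjusted p = 1.67e-07, and adjusted p = 0.222 with an estimated correlation). Wnt8b was not called without vehicle 8 (adjusted p = 0.0654), nor Wnt5a without vehicle 7 or vehicle 8 (up to 0.077). Among Cajal-Retzius cells, early neurons that arise partly from the hem, 4 of 10 members rose, 0 fell and 6 did not pass (5 rose adjusted over the list alone). These were Ebf3, Lhx1, Lhx5 and Trp73, at 0.95, 1.55, 1.22 and 0.94 on the log2 scale, and each lost its call without vehicle 8 (Ebf3), without any 1 vehicle embryo (Lhx1), or without these and FGF2 7 (Trp73) or FGF2 6 or 7 (Lhx5), at an adjusted p of up to 0.0628, 0.0666, 0.126 and 0.14. Reln, their secreted product, chosen after its values were seen, was at 108 ± 26.5 against 123 ± 13.7 CPM and did not pass. The Cajal-Retzius list had a camera adjusted p of 0.000609 and an adjusted p = 0.196 with an estimated correlation. Wnt and beta-catenin targets counted 2 that rose (Sp5, to 9.61 ± 2.45 from 1.89 ± 0.147 CPM, and Tcf7l2, by 2.01), 0 that fell and 10 that did not pass of 12 (8 rose adjusted over the list alone), with a camera adjusted p of 0.000201 and an adjusted p = 0.222 with an estimated correlation. Tcf7l2 was not called without FGF2 6, FGF2 8 or any 1 vehicle embryo (adjusted p up to 0.138).

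**Figure D1:**
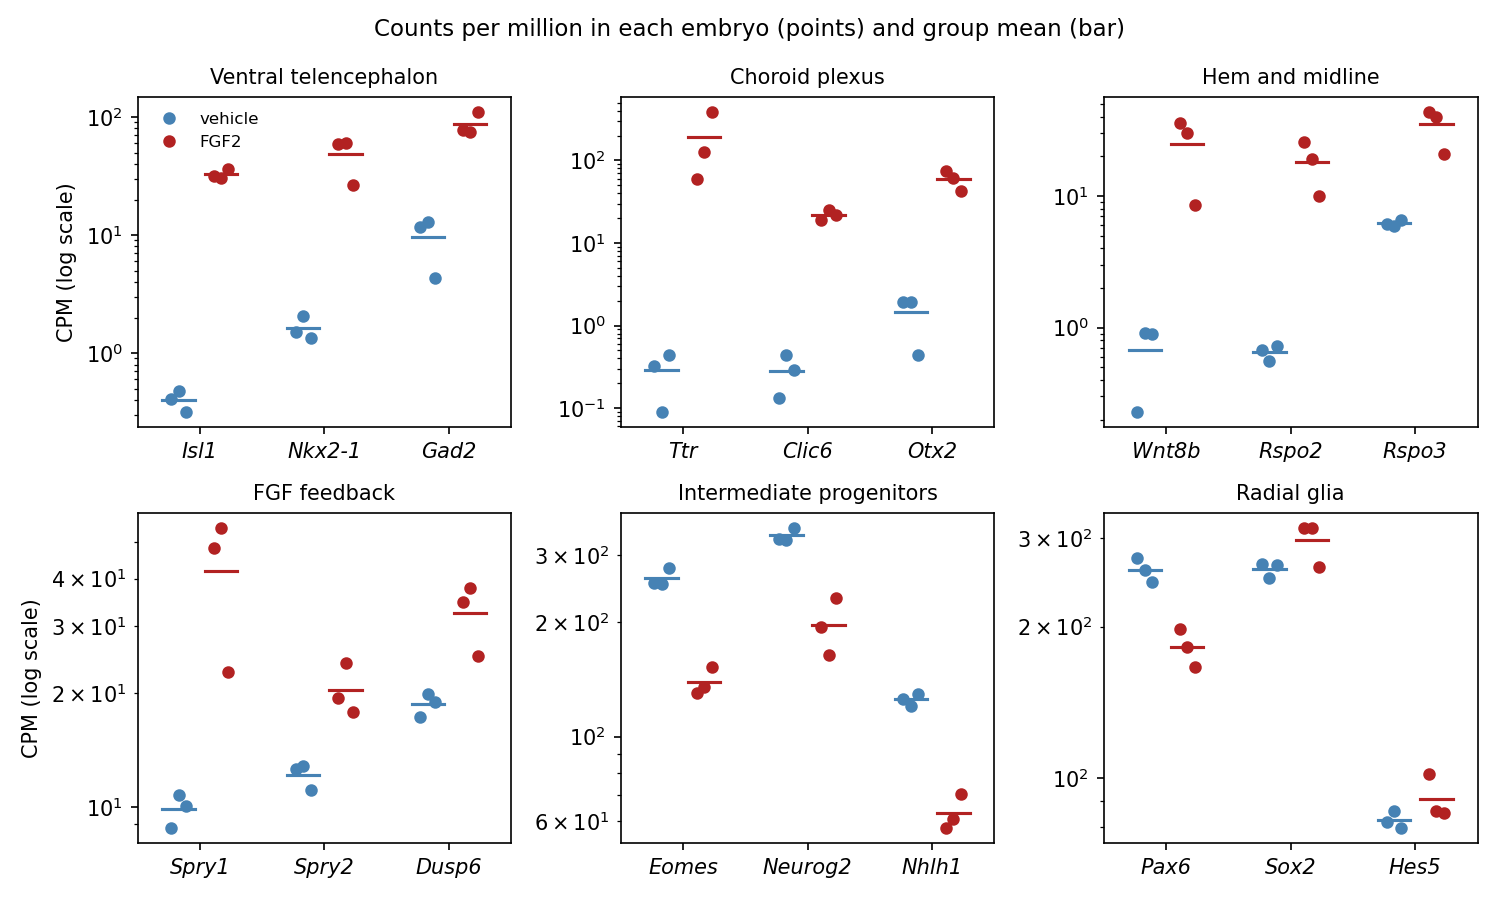
CPM of 18 genes in each embryo on log axes, as points, with the group mean as a bar, in 3 FGF2 embryos (red) and 3 vehicle embryos (blue). Isl1 stood at 32.8 in the FGF2 mean against 0.402, and Eomes at 139 against 262, with no overlap between the groups for either gene.

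Genes that FGF signalling induces as its own feedback inhibitors rose in part. Spry1 rose to 41.8 ± 16.9 from 9.86 ± 0.983 CPM (SD, n = 3, edgeR adjusted p = 0.0132), Spry2 by 0.75 and Dusp6, a phosphatase of the ERK kinases, by 0.80 on the log2 scale. Etv5, an FGF-induced transcription factor, was at 30.1 ± 4.65 against 40.7 ± 8.9 CPM and Spry4 at 7.9 ± 0.678 against 4.88 ± 0.646 CPM, and neither passed. Of 20 measured feedback and target genes 3 rose, 0 fell and 17 did not pass (7 rose and 1 fell adjusted over the list alone), with a median of 0.42. The list was higher with camera (adjusted p = 0.0112, and adjusted p = 0.32 with an estimated correlation). The calls of Spry1 were lost without any 1 vehicle embryo (adjusted p up to 0.0834), and those of Spry2 and Dusp6 also without FGF2 6 or FGF2 7 (up to 0.124 and 0.163). In the fits without 1 embryo the log2 fold changes of Spry1, Spry2 and Dusp6 were 1.85 to 2.38, 0.61 to 0.84 and 0.68 to 0.96. Whether the injected FGF2 or a difference in the regions sectioned gave these rises was not tested.

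Among FGF ligands and receptors, 4 ligands rose. Fgf17 rose by 5.17, Fgf15 by 3.69 and Fgf3 by 3.94, and Fgf8 stood at 8.16 ± 6.5 against 0.0598 ± 0.104 CPM. Fgf2 itself was at 12.8 ± 1.62 against 12.8 ± 0.804 CPM, a log2 fold change of 0.00 ± 0.13 (SE), over a gene span that overlaps 5 others. The receptors Fgfr1 and Fgfr3 did not pass, at 148 ± 9.68 against 160 ± 6.28 and 63.3 ± 11.2 against 73.9 ± 23.5 CPM, and the span listed for Fgfr2 overlaps 41 other genes, so its counts are not those of Fgfr2 alone. Of 23 measured members 4 rose, 0 fell and 19 did not pass (7 rose adjusted over the list alone), with a median of 0.54 and a camera adjusted p of 0.00333 (adjusted p = 0.222 with an estimated correlation). Fgf8 was not called without FGF2 6, FGF2 7 or any 1 vehicle embryo (adjusted p up to 0.127), and the list was not called when only genes overlapping no other span were kept (adjusted p = 0.0599).

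In the lists of cortical patterning, members of both the rostral and the caudal group rose. Of 12 rostral genes 5 rose (Fgf8, Fgf17, Spry1, Spry2 and Dusp6, which are also FGF genes), 1 fell (Pax6) and 6 did not pass, with 6 risen and 1 fallen adjusted over the list alone, a median of 0.58 and a camera adjusted p of 0.0112 (adjusted p = 0.467 with an estimated correlation). Of 10 caudal genes 4 rose, 0 fell and 6 did not pass (5 rose adjusted over the list alone), with a median of 0.50 and a camera adjusted p of 0.00146 (adjusted p = 0.222 with an estimated correlation). The 4 were Wnt8b, which is also a hem gene, Ephb1, a guidance receptor, which rose by 1.69, Nr2f2, a nuclear receptor of caudal and ventral territories, which rose by 1.04, and Crym, which rose to 11.1 ± 6.79 from 2.18 ± 0.24 CPM. Crym was not called without any 1 vehicle embryo (adjusted p up to 0.125), and the caudal list was not called when only genes overlapping no other span were kept (adjusted p = 0.123).

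Intermediate progenitors, the basal dividing cells that produce most cortical neurons, showed the opposite direction. Eomes, their defining transcription factor on chromosome 9 (118387330 to 118395250), fell by 0.91 ± 0.09 (SE, edgeR adjusted p = 0.00288), from 262 ± 14.8 to 139 ± 11.7 CPM (SD, n = 3). Nhlh1 fell to 62.8 ± 6.77 from 125 ± 4.42 CPM, Neurog1 by 0.72 and Neurog2 by 0.79 on the log2 scale, all 3 transcription factors of the neurogenic programme. Of 14 measured members 5 fell, 0 rose and 9 did not pass (9 fell adjusted over the list alone), with a median of -0.64. Other dorsal pallium markers, 12 chosen after most of their values were seen, were lower too, with a median of -0.73 and 2 called (Emx1 and Tfap2c). The intermediate progenitor list was lower with camera (adjusted p = 7.3e-09, and adjusted p = 0.222 with an estimated correlation). Neurog1 was not called without vehicle 7 or vehicle 8 (adjusted p up to 0.0634), and Neurog2 without FGF2 6 or any 1 vehicle embryo (up to 0.0856).

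Radial glia are the stem cells that line the ventricle, and few of their genes passed. Pax6, their dorsal transcription factor, fell by 0.51, from 259 ± 14.2 to 182 ± 16.1 CPM (SD), and Sox9 and Aldoc fell by 0.59 and 1.21, while Sox2 and Hes5 were at 297 ± 29.6 against 261 ± 9.11 and 90.9 ± 9.31 against 82.4 ± 3.29 CPM and did not pass. Of 21 members 3 fell, 0 rose and 18 did not pass, also adjusted over the list alone, with a median of -0.24 and a camera adjusted p of 0.0294 (adjusted p = 0.579 with an estimated correlation). Without FGF2 8 or vehicle 7 the radial glia list was not called (adjusted p up to 0.266, with a median of -0.08 without FGF2 8). Nor was it with a minimum of 1 CPM in 3 libraries (0.0565), with voom and sample quality weights (0.123), with RPKM plus 1 or plus 0.1 (0.0527 and 0.057) or on genes overlapping no other span (0.241). The calls of Pax6 and Sox9 were lost without any 1 vehicle embryo, and without FGF2 7 and FGF2 6 respectively (up to 0.14 and 0.175). Of 12 outer radial glia genes, a list drawn up for the basal stem cells of folded cortices, 0 passed in either direction, also adjusted over the list alone (camera adjusted p = 0.567, and adjusted p = 0.676 with an estimated correlation). Of 16 Notch pathway genes 0 passed over all genes, and 1 was lower adjusted over the list alone (camera adjusted p = 0.0898, and adjusted p = 0.453 with an estimated correlation). The Notch list was called as lower without FGF2 7 (adjusted p = 0.0423), without a low-count filter (0.045) and with the embryo number as a block (0.0318).

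Few cortical projection neuron genes passed. Nefm, a neurofilament subunit, rose by 1.17 ± 0.10 (SE), from 23.7 ± 2.43 to 53.5 ± 2.43 CPM, and Nefl, another subunit, from 6.16 ± 1.88 to 15.3 ± 1.47 CPM. The span of Nefl lies inside that of Nefm, so these calls are not separate, and Nefl was not called without FGF2 6, FGF2 7, vehicle 8 or vehicle 9 (adjusted p up to 0.086). Ina, a related subunit, was at 198 ± 49 against 119 ± 10.1 CPM and Tbr1, a deep-layer transcription factor, at 174 ± 43.7 against 288 ± 26.3 CPM, and neither passed. Of 23 measured members 2 rose, 0 fell and 21 did not pass (3 rose and 2 fell adjusted over the list alone), with a median of -0.19 and a camera adjusted p of 0.431 (adjusted p = 0.835 with an estimated correlation). The share of all reads in this list was 0.435% in FGF2 8, against 0.254% and 0.266% in FGF2 6 and 7 and 0.332% to 0.345% in the vehicle embryos. Without FGF2 8 the list was lower, at a median of -0.39 (adjusted p = 0.000207). It was also lower with voom and sample quality weights (adjusted p = 0.0102) and on genes overlapping no other span (0.0446).

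Cell cycle genes were lower as lists without a single member past the test. Of 21 DNA replication genes 0 passed (camera adjusted p = 0.0112, and adjusted p = 0.585 with an estimated correlation) and of 20 mitosis genes 0 passed (camera adjusted p = 0.00255, and adjusted p = 0.585 with an estimated correlation), also adjusted over the list alone, with medians of -0.24 and -0.18. Mki67, a marker of cycling cells, was at 404 ± 63.1 against 416 ± 32.5 CPM. Both list calls were lost without FGF2 8, where the medians were -0.06 and -0.02 (camera adjusted p = 0.431 and 0.267). FGF2 8 had 0.190% and 0.243% of its reads in these lists against 0.282% to 0.292% and 0.335% to 0.352% in the other 5 libraries. Both calls were also lost with voom and sample quality weights (adjusted p = 0.202 and 0.148). That of DNA replication was lost with RPKM plus 0.1 (0.0549) and that of mitosis on genes overlapping no other span (0.0507). Of 11 G1 regulators, Cdkn1a, a cell cycle inhibitor, rose by 1.16, Ccnd2, a cyclin of cortical progenitors, fell by 0.83 and 9 did not pass, Ccnd1 among them (2 rose and 5 fell adjusted over the list alone). That list had a camera adjusted p of 0.0632 and an adjusted p = 0.467 with an estimated correlation, and Ccnd2 was not called without FGF2 6 or any 1 vehicle embryo (adjusted p up to 0.131). The G1 list was called as lower without FGF2 7 (adjusted p = 0.0173), without a low-count filter (0.0352) and on RPKM plus 1 without a filter (0.0251). Of 50 measured replication-dependent histones 1 fell (Hist2h2be), 0 rose and 49 did not pass, with 0 adjusted over the list alone (camera adjusted p = 0.278, and adjusted p = 0.676 with an estimated correlation), and Hist2h2be was not called without FGF2 6, FGF2 7 or any 1 vehicle embryo (adjusted p up to 0.194). The histone list was called as higher without FGF2 6 (adjusted p = 0.0214) and with the embryo number as a block (0.0353).

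Glial, p53 and stress genes had few members past the test. In the glial lineage Olig1 and Olig2, transcription factors of oligodendrocyte and ventral progenitors, rose by 3.76 and 2.87, and Sox10 by 3.57. Of 10 members 3 rose, 0 fell and 7 did not pass (4 rose adjusted over the list alone), with a camera adjusted p of 0.00151 and an adjusted p = 0.222 with an estimated correlation. Of 12 p53 targets 2 rose, 0 fell and 10 did not pass, also adjusted over the list alone (camera adjusted p = 0.392, and adjusted p = 0.585 with an estimated correlation). The 2 were Cdkn1a and Pmaip1, which stood at 7.36 ± 3.68 against 1.31 ± 0.222 CPM. Of 13 stress and immediate early genes 1 rose (Gadd45a, by 0.73), 0 fell and 12 did not pass, with 1 risen and 1 fallen adjusted over the list alone (camera adjusted p = 0.619, and adjusted p = 0.814 with an estimated correlation). The calls of Sox10, Pmaip1 and Gadd45a were each lost without any 1 vehicle embryo and without 2 of the FGF2 embryos, 7 and 8 for Sox10 and 6 and 7 for the others (adjusted p up to 0.141, 0.119 and 0.163).

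Markers of other cell types differed between the groups as well. Among microglia and macrophage genes, Trem2 rose to 4.27 ± 0.654 from 1.71 ± 0.398 CPM. Ptprc was higher by 1.23, Tyrobp by 1.19 and C1qb by 0.92 on the log2 scale. Of 13 members 6 rose, 0 fell and 7 did not pass (11 rose adjusted over the list alone), with a median of 0.91 and a camera adjusted p of 6.46e-08 (adjusted p = 0.222 with an estimated correlation). Each of the 4 named genes lost its call without FGF2 7 or any 1 vehicle embryo, and Trem2 also without FGF2 6 (adjusted p up to 0.106 for Ptprc, 0.114 for Tyrobp, 0.108 for C1qb and 0.124 for Trem2). In the diencephalon and midbrain list Gbx2 rose, 0 fell and 6 of 7 did not pass (4 rose adjusted over the list alone), with a median of 0.84 and a camera adjusted p of 0.0107 (adjusted p = 0.222 with an estimated correlation), a call lost with the stricter minimum of 1 CPM in 3 libraries (adjusted p = 0.0507), on RPKM (0.0537 to 0.223) and on genes overlapping no other span (0.181). Of 14 meningeal and mesenchymal genes Foxd1 rose by 1.13, Col1a1 and Col1a2, the chains of type I collagen, fell by 0.92 and 0.71, and 11 did not pass (2 rose and 3 fell adjusted over the list alone). That list had a median of 0.05, while camera gave the lower direction (adjusted p = 0.26, and adjusted p = 0.585 with an estimated correlation). Foxd1 was not called without FGF2 6, FGF2 7 or any 1 vehicle embryo (adjusted p up to 0.196), nor Col1a2 without FGF2 7, vehicle 7 or vehicle 9 (up to 0.0975).

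The remaining lists had at most 1 member past the test. Of 10 red blood cell genes 0 passed over all genes and 1 was higher adjusted over the list alone (higher with camera, adjusted p = 0.0151, and adjusted p = 0.453 with an estimated correlation), and the list call was lost without FGF2 7, vehicle 7 or vehicle 9 (adjusted p up to 0.0785). It was also lost without mitochondrial, haemoglobin, ribosomal RNA and the 10 most abundant genes (0.207) and in the RPKM fits (0.119 to 0.141). Of 14 endothelial and pericyte genes 0 passed, also adjusted over the list alone (higher with camera, adjusted p = 0.0133, and adjusted p = 0.488 with an estimated correlation), and that call was lost without FGF2 8 or vehicle 9 (up to 0.108). It was also lost with the embryo number as a block (0.0506), voom and sample quality weights (0.135) or sex as a covariate (0.342), and on genes overlapping no other span (0.101). Of 9 skin and muscle genes 0 passed and 2 were higher adjusted over the list alone (camera adjusted p = 0.0983, and adjusted p = 0.579 with an estimated correlation). The skin and muscle list was called as higher without FGF2 6 (adjusted p = 0.0188) or vehicle 8 (0.018), without a low-count filter (0.0404), with the block (0.0289) and with sex as a covariate (0.0283). Of 18 genes of brain extracellular matrix and adhesion 0 passed and 1 was higher adjusted over the list alone (camera adjusted p = 0.215, and adjusted p = 0.624 with an estimated correlation). Of 84 ribosomal protein genes 1 rose (Rpl34, to 53.7 ± 4.76 from 35.8 ± 3.48 CPM), 0 fell and 83 did not pass, with 0 adjusted over the list alone, a median of 0.28 and a camera adjusted p of 3.42e-10 (adjusted p = 0.257 with an estimated correlation). Rpl34 was not called without FGF2 7 or any 1 vehicle embryo (adjusted p up to 0.113). Of 36 mitochondrially encoded genes 0 passed, also adjusted over the list alone (higher with camera, adjusted p = 0.0342, and adjusted p = 0.676 with an estimated correlation). The share of reads from mitochondrial genes was 3.83% in FGF2 8 and 2.42% to 2.64% in the other 5 libraries, and without FGF2 8 or vehicle 7 the mitochondrial list was not called (up to 0.814). Nor was it with voom and sample quality weights (0.669) or on genes overlapping no other span (0.101). In the outer radial glia and extracellular matrix lists the mean had the opposite sign to the median and the test, 0.02 against -0.13 and 0.03 against -0.06.

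**Figure D2:**
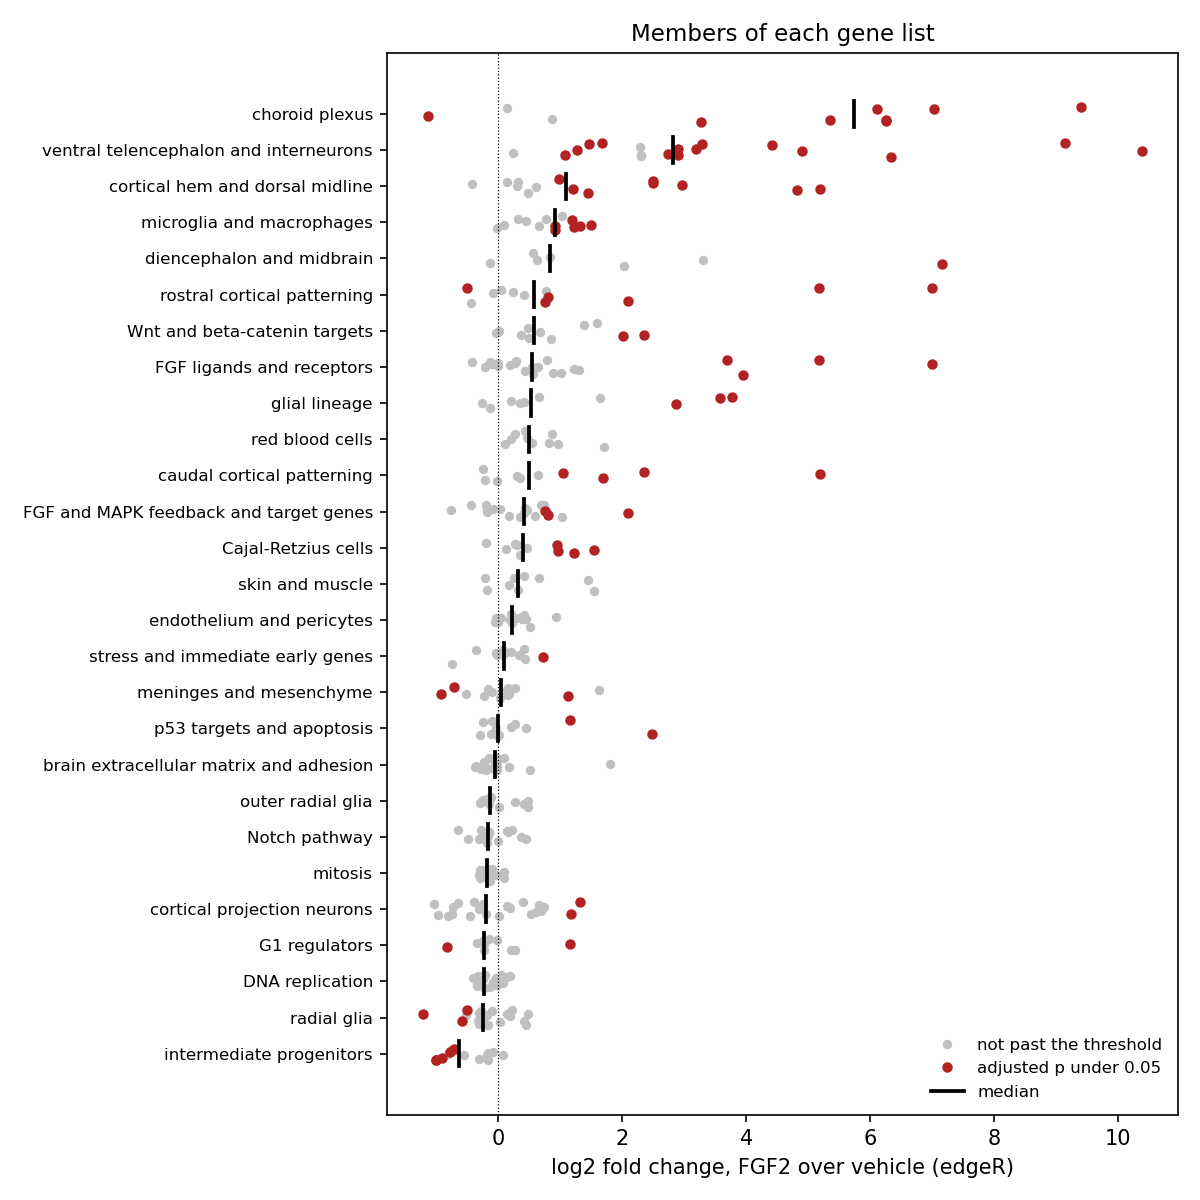
Log2 fold change of FGF2 over vehicle for the measured members of 27 gene lists, with members past an adjusted p of 0.05 in red, other members in grey and the list median as a black bar. The medians reach from -0.64 for intermediate progenitors to 5.74 for the choroid plexus.

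With camera and its preset correlation, 16 lists were higher and 4 were lower past an adjusted p of 0.05, and 0 of the 30 lists were called with an estimated correlation, where the lowest adjusted p was 0.196. The rotation test fry, which does not compare a list with other genes, called 8 lists. These were the ventral telencephalon, choroid plexus, intermediate progenitor, Cajal-Retzius, FGF ligand and receptor, caudal patterning, glial and microglia lists. The hem list was not among them (fry adjusted p = 0.0508), nor was the FGF feedback list (0.0761). Embryo sex is nearly aligned with the groups, and with sex as a covariate, where the contrast rests on vehicle 7 alone, 5 genes were called, although all 799 kept their direction. With that covariate 16 lists were higher and 4 lower past the same threshold, among them 19 of the 20 called without it. The medians were then 2.50 for the ventral telencephalon, 5.85 for the choroid plexus and 1.16 for the hem, with adjusted p = 9.78e-22, 7.71e-05 and 1.68e-07 from camera. Leaving out 1 embryo gave 218 (without vehicle 8) to 1943 (without FGF2 8) called genes, with 242 without vehicle 7, 307 without vehicle 9, 405 without FGF2 7 and 517 without FGF2 6. Of the 799 genes, 231, 214 and 288 kept their call without vehicle 7, 8 and 9, and 440, 366 and 758 without FGF2 6, 7 and 8. Loss of a call in a fit with fewer embryos is thus common and does not by itself show that a gene depends on that embryo.

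Other settings also ended calls of named genes, beside the losses given above for single embryos. With sex as a covariate 70 of the 73 called named genes were lost. The embryo number as a block ended 19 calls, those of Actn3, Ccnd2, Col1a2, Dusp6, Fgf8, Gadd45a, Hist2h2be, Pamr1, Pax6, Ptprc, Rpl34, Sox9, Spry1, Spry2, Tacr3, Tcf7l2, Tnn, Trem2 and Wnt8b. Without a low-count filter 5 were lost (Fgf8, Gbx2, Pitx1, Tcf7l2 and Wnt8b), with voom and sample quality weights 6 (Fgf8, Gbx2, Pitx1, Tcf7l2, Tnn and Ttr), and with library totals alone 2 (Sox9 and Hist2h2be). RPKM plus 0.1 kept 51 calls and ended 6 (Dusp6, Foxd1, Hist2h2be, Pax6, Sox9 and Tcf7l2). RPKM plus 1 kept 48 and ended these 6 and those of Crym, Fgf8 and Pmaip1. The other called named genes did not enter these filtered fits. RPKM plus 1 without a filter ended 33 calls. These were the 9 lost with RPKM plus 1 and those of Actn3, Aldoc, Ccnd2, Col1a2, Dct, Gadd45a, Gbx2, Htr2c, Lhx1, Lhx5, Neurog2, Onecut3, Pamr1, Pitx1, Ptprc, Rpl34, Sox10, Spry1, Spry2, Tacr3, Tnn, Trem2, Trp73 and Wnt5a. Calls were gained too among the 74 named genes not called, 26 with DESeq2, 22 with voom and sample quality weights, 17 without FGF2 8 and at most 7 in each other setting. Of the genes given above as not passing, Tbr1 was called as lower in these 3 fits and Ina as higher. Sox2 was called as higher with voom weights and without FGF2 8, Spry4 as higher with DESeq2 and voom weights, and Ccnd1 as higher without FGF2 8.

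In log2 CPM of the 500 most variable genes, the first principal component held 59% of the variance and separated the FGF2 embryos from the vehicle embryos, and 56% of the variance lay between the groups (44.8% over all genes kept). The second component held 25.6% and set vehicle 9 (35.73) apart from vehicle 7 (-26.46) and vehicle 8 (-24.83). Without vehicle 9 the share between the groups was 69%. Spearman correlations between libraries were 0.984 to 0.992 within the FGF2 group, 0.988 to 0.994 within the vehicle group and 0.974 to 0.985 between the groups. Counts of each pair of libraries differed by more than sampling noise, with chi-square values of 16 to 128 per degree of freedom, so no library was counted as a duplicate.

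**Figure D3:**
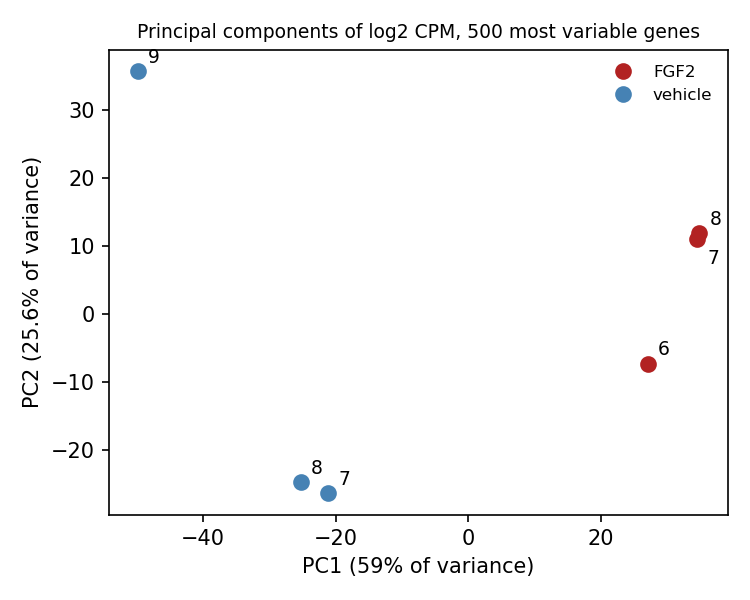
First and second principal component of log2 CPM over the 500 most variable genes, 1 point per embryo with its number, FGF2 in red and vehicle in blue. The 3 FGF2 embryos lie at 27 to 34.81 on the first component and the 3 vehicle embryos at -49.84 to -21.13.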

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

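The alternatives that halved vehicle 9, kept only genes overlapping no other span or left out the X and Y chromosomes were chosen after seeing the data. The count of 799 called genes lay within 1.5 times of that value with other scalings, filters, the gene length offset, the removal of abundant genes, halved counts of vehicle 9 (823) and no X and Y genes (789). It was 2259 with voom and sample quality weights, 2065 with DESeq2, 432 with RPKM plus 1, 431 with RPKM plus 0.1, 271 with RPKM plus 1 and no filter and 5 with embryo sex as a covariate, and the cause was not tested. It was 488 among the 10826 genes that overlap no other span, where fewer genes were tested. The filtered fits on RPKM plus 1 and RPKM plus 0.1 also tested fewer genes, 13894 each, with 507 of the 799 called genes among them. Leaving out 1 embryo gave 218 to 1943 genes. All 799 genes kept their direction in each of these left-out fits, and 31 of the 73 called named genes kept their call in each, with both identifiers of Lhx8 counted. The 20 called lists became 0 with an estimated correlation and 8 with fry, and 16 to 22 without 1 embryo, where 14 of the 20 kept their call throughout. The share of variance between the groups (56%) was 44.8% over all genes and 51.3% to 69% without 1 embryo. The embryo number as a replicate block gave 703 genes and 22 lists, but 7 and 8 are the only shared numbers, and their deviations correlated at -0.038 and -0.03, so the numbers are no evidence of pairing. Directions (for lists, that of camera's test, while a median need not change sign) reversed in 28 cases, and 0 of these were called under the alternative. The mitochondrial list, called as higher before, had a median of 0.02 without FGF2 8 and camera's direction was lower. The other reversed results were not called to begin with. List medians were, for projection neurons, -0.03 without FGF2 6, -0.06 without FGF2 7, -0.03 with the block and -0.08 with sex as a covariate, and they spanned -0.39 to -0.03 without 1 embryo. They were, for histones, 0.11 with the 1 CPM minimum, 0.06 with RPKM plus 1 and 0.05 with RPKM plus 0.1, for stress genes 0.04 without FGF2 7 and 0.05 without vehicle 7 (up to 0.25 without 1 embryo), and for outer radial glia 0.01 on genes overlapping no other span. Log2 fold changes of Fgf2 were -0.01 with RLE, -0.11 without FGF2 6, -0.05 without vehicle 9, -0.16 with the block, -0.01 without the abundant genes, -0.07 with sex as a covariate and -0.01 with DESeq2. Mki67 was at 0.06 without FGF2 8, 0.01 without vehicle 9, 0.05 with voom weights and 0.01 in each of the RPKM fits, Fgfr3 at 0.06 without vehicle 8 (down to -0.39 without vehicle 7) and 0.18 with sex as a covariate, Ccnd1 at -0.03 with the block and Xist at 0.39 with sex as a covariate. The cause was not tested for these reversals. The planned use of the most-read row per gene was not run, because each gene has 1 row. Depth limits genes with few vehicle reads, such as Shh and Pitx1, whose ratios have wide intervals, and Gsx1, which has only a lower bound.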

Other observations

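Tests of the vehicle 9 counts, embryo sex, hypothalamus, pituitary and face, and dorsal pallium were chosen only after the results they bear on were seen, while the subpallium genes and the splits of the libraries were set before. The FGF2 embryos were not alike in the genes that rose. The thalamic gene Gbx2 and Tcf7l2 were lowest in FGF2 7, and Wnt8b, Spry1 and Fgf17 were lowest in FGF2 8, the embryo with the most Ttr. FGF2 8 also had the lowest shares of reads in the radial glia list (0.380%, against 0.484% and 0.487% in FGF2 7 and 6) and in the hem list (0.0161%, against 0.0267% and 0.0336%), and the highest in the ventral list (0.124%, against 0.108% and 0.0959%). These differences between single embryos have no test.

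As lists, genes of the ventral telencephalon, choroid plexus and dorsal midline were higher in the FGF2 embryos. The even counts of vehicle 9 do not account for it, since doubling leaves CPM values unchanged, and without that embryo the 42 measured members of these 3 lists had a median log2 fold change of 2.44 (SD 3.09), with 26 past the test. With sex as a covariate the ventral, choroid plexus and hem lists were still called as higher with camera's preset correlation, at medians of 2.50, 5.85 and 1.16, while without the covariate none was called with an estimated one (adjusted p = 0.196 to 0.222). Over those 42 genes the FGF2 mean exceeded vehicle 7 by a median of 2.34 (SD 2.59). Both results rest on vehicle 7, the one vehicle embryo with Y-linked reads, so sex is not excluded. Sections that took in more tissue beyond the dorsal pallium may also give this pattern: 6 other subpallium genes had a median of 0.07 (SD 0.56), under the bound of 0.2 that was set beforehand as evidence against it, but by less than their spread. Rarb was higher, Nkx6-2 was at 4.53 against 2.68 CPM without passing, Sox6 was lower, and Foxp1, Foxp2 and Meis2 were already abundant in the vehicle embryos, so this was not taken as exclusion. That criterion of spread was added only after the value was seen, and an SD between genes does not measure the error of a median. Lists for the hypothalamus (median 0.81, 4 measured) and for the pituitary and face (median 3.62, 8 measured) were written after Bsx and 6 of those 8 genes had been seen among the calls, which makes them no independent evidence.

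Vehicle 9 stood apart on the second principal component, and 100% of its non-zero counts were even, against at most 51.88% elsewhere. Its halved counts showed 0.602 genes with 2 reads for each gene with 1, where the other libraries had at least 1.19, which is consistent with mates not being counted as separate reads in that library. Doubling of separately counted mates would leave more genes with 2 halved reads than with 1, as in the other libraries. Counting each alignment 2 times without separate mates and counting each read pair as 2 cannot be told apart, since both give even counts and that ratio. Doubling multiplies every count of a library alike and so leaves its CPM values unchanged. The position on the second component has no tested explanation, technical or biological. Vehicle 9 was also low in ventral genes, with 0.0201% of its reads in that list against 0.0352% and 0.0333% in vehicle 7 and 8. Dlx2, chosen after its values were seen, was at 4.79 CPM against 37.3 and 25.9.

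Intermediate progenitor genes were lower in the FGF2 embryos, with a median of -0.64. A smaller share of dorsal pallium in the sections may give such a fall: 12 other dorsal pallium markers had a median of -0.73 (SD 0.31), with 12 of 12 lower and 2 called. This cannot be told apart from an effect of FGF2 on these cells, because the values of most of the 12 had been seen when they were chosen, and the 2 that had not, Dmrta2 and Bhlhe22, were at -0.52 and -0.87. An effect of the injection is among the open explanations for this pattern and for the rise of ventral, choroid plexus and midline genes, and neither is settled here. The rise of FGF ligands and feedback genes was not tested against a difference in the regions sectioned, so its source is open too.

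Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split gave 799 genes and 20 lists and was the 1 split with results that large. The others gave 0 to 13 genes and 6 to 15 lists. Each of these mixes FGF2 and vehicle embryos on both sides, so a difference between the groups would itself widen the spread and leave few genes. The gene counts of the other splits therefore cannot measure chance. With the preset correlation, lists were called in every split. The other splits place unequal numbers of FGF2 embryos on their sides, so part of a group difference stays in them. Their list counts therefore cannot measure chance either, and how often such calls arise under wrong labels stays open.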
